A study of Arabidopsis thaliana with 24 samples.

How the data were processed

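Root RNA of 6-week-old Arabidopsis thaliana plants grown in hydroponic culture was measured on 24 Affymetrix ATH1 arrays, a 1-colour microarray on which each gene is read by a set of short probes. Some labels speak of seedling roots and others of 6-week-old plants, and the age of 6 weeks was used here. Col-0 wild type and the double mutant bzip1/bzip53 were each sampled without added salt and after 1 h, 3 h and 6 h in 150 mM NaCl, with 3 arrays in each of the 8 groups. The titles call the arrays of a group biological replicates, and the labels do not say how plants or cultures were divided between them, so the p-values measure the spread between these arrays. The protocol states that salt-treated roots of both genotypes were harvested together at a fixed time of the light period, and gives no separate time for the untreated roots.

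The deposited values are on a log2 scale, as inferred from their range of 2.46 to 14.04, and RMA, affy and limma are the tools named, per the submitters' processing notes, which give no versions and name TAIR9 as the build. RMA corrects background, equalises the distribution of intensities between arrays and summarises the probes of a probe set. The order and settings of these steps are not given in the sources used here. Array medians lay between 6.53 and 6.67, the correlation between 2 arrays of a group between 0.985 and 0.997, and no more than 0.0352% of values were identical between 2 arrays. The scanner files were not analysed here.

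The table held 22810 probe sets. The 64 Affymetrix control probe sets were left out, and 22746 were tested. The platform's gene table gave 1 gene symbol for 13513 probe sets, several for 503 and none for 8730, and only probe sets with 1 symbol were named. Symbols were updated through Entrez identifiers with an NCBI RefSeq gene table of assembly TAIR10.1, used only for names. It matched 13436 of the 13513, the other 77 kept their older name, and 13355 genes were named in all. Names such as AT2G41730 are locus codes of genes without a symbol there. A gene with several probe sets (147 genes) was named from the one with the highest mean over all arrays. In 1 of these genes, 2 probe sets were called in opposite directions in wild type at 6 h. No probe set was named as bZIP1 in the gene table used here.

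All 24 arrays entered 1 limma fit (version 3.58.1, R 4.3.3) of the 8 group means with moderated two-sided tests, 16 residual degrees of freedom and 3.83 prior degrees of freedom. A probe set was called at an adjusted p under 0.05 after Benjamini-Hochberg adjustment over the 22746 probe sets of a comparison. The comparisons were salt against control in each genotype at each time, 3 h against 1 h and 6 h against 3 h in wild type, mutant against wild type in each of the 4 conditions and over their mean, and the difference of the salt responses (mutant minus wild type) at each time. The samples, tests, gene lists and the rule for named genes were fixed before the data were examined. That rule took probe sets with 1 gene, a call and no overlap between the 3 arrays of each group. It named the 8 highest and 8 lowest for wild type under salt, the 6 highest and 6 lowest for mutant against wild type, the 8 with the smallest p for a difference of responses (overlap not asked), the targeted genes, and up to 4 members of each fixed list whether or not they passed. With 3 arrays against 3, non-overlap arises by chance in 10% of probe sets. Errors are standard deviations (SD) of 3 arrays for levels and standard errors (SE) of the fit for differences, and folds are powers of 2 of the log2 differences.

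Gene lists were tested by limma's camera with a preset inter-gene correlation of 0.01, adjusted over the 29 lists tested per comparison. Each list was compared with 1 probe set for each other named gene and with all probe sets that had no symbol or several. Of the 27 lists fixed in advance, with 318 genes, 43 genes were named in the gene table and 3 lists had at least 3 measured members, namely the desiccation genes (6 measured), the branched-chain amino acid breakdown genes (10) and the autophagy genes (7). A further 26 lists were set up from gene families after the gene names had been seen. One list of 24 hypoxia-response genes was written after the leading genes of the 3 h genotype comparison were known. With a correlation estimated from the data instead, 1 of the 82 list calls held, that of the plastid-encoded genes in the difference of responses at 6 h. For that reason the adjusted p with an estimated correlation is printed beside list calls.

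The fit was tested on simulated data of 22746 probe sets with the wild-type control means and the real spreads, drawn independently for each probe set. For wild type at 3 h against control the fit recovered 50.7%, 95.5% and 98.5% of changes of 0.5, 1 and 2 (log2), set in 67, 67 and 66 probe sets, with 3.55% false calls. For the difference of responses at 3 h it recovered 19.4%, 80.6% and 100%, with 3.62% false calls, and for the mean genotype difference 94.0%, 95.5% and 100%, with 2.53% false calls. The real probe sets varied together within groups, along 1 direction with 37.5% of the variance, and far more of them were called under salt. These rates therefore need not hold for the real arrays. Alternatives were each array centred on its median, quantile normalization repeated, a trended and robust prior, array weights, only the arrays compared in the fit, the replicate number as a block, no dim probe sets (the 30% with the lowest mean), a threshold of 0.01, a fold of at least 2, and each array left out in turn. For gene lists they were the estimated correlation, the rotation test fry, the block and the mean of all probe sets of a gene. The median log2 difference over all probe sets stayed between -0.0849 and 0.0197 in every comparison.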

Results

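Transcript levels were measured in roots of 6-week-old Arabidopsis plants, of wild type and of the double mutant bzip1/bzip53, without added salt and after 1 h, 3 h and 6 h in 150 mM NaCl. The mutant carries lesions in 2 genes for bZIP transcription factors, and the title of the series places them in the reprogramming of root metabolism under salt. Each of the 8 groups had 3 arrays, each array read 22746 tested probe sets on a log2 scale, and array medians ran from 6.53 to 6.67. Adjusted p values are from limma with Benjamini-Hochberg adjustment. Log2 differences and folds in which 1 group lay near the background (a log2 level under 5) have no exact size.

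The targeted gene BZIP53 (AT3G62420) was lower in all 12 mutant arrays than in any wild-type array, which checks the genotype labels. Its wild-type level was 10.57 ± 0.26 in the control, 11.01 ± 0.09 at 1 h, 11 ± 0.12 at 3 h and 10.93 ± 0.086 at 6 h (log2, SD, n = 3). In the mutant it was 9.19 ± 0.041, 8.75 ± 0.074, 8.86 ± 0.036 and 9.004 ± 0.12. The mutant was thus lower by 2.60-fold in the control and by 4.82-fold, 4.40-fold and 3.80-fold at 1 h, 3 h and 6 h (adjusted p = 2.18e-07, 3.94e-11, 9.98e-11 and 4.43e-10), and some signal remained. The position of the probe set relative to the lesion is not given in the sources used here. BZIP53 rose slightly with salt in wild type, by 0.45, 0.43 and 0.36 (log2, SE 0.102), and fell in the mutant at 1 h (-0.45) and 3 h (-0.33). The wild-type call at 6 h was lost without control array 1 (0.26, adjusted p = 0.0518). The probe set with the largest genotype difference has no gene in the gene table used here and was singled out after its values were seen. It stood at 8.26 ± 0.16 in the wild-type control and 4.42 ± 0.17 in the mutant control, and the mutant minus wild-type difference was -3.84 in the control, -4.11 at 1 h, -3.94 at 3 h and -5.24 at 6 h (log2), as the plot of BZIP53 and this probe set shows. Mutant levels near the background in the control (4.42) and at 6 h (4.96) leave the differences there without an exact size. At 1 h and 3 h the mutant levels, 5.32 and 5.38, lay just above the bound of 5.

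**Figure D1:**
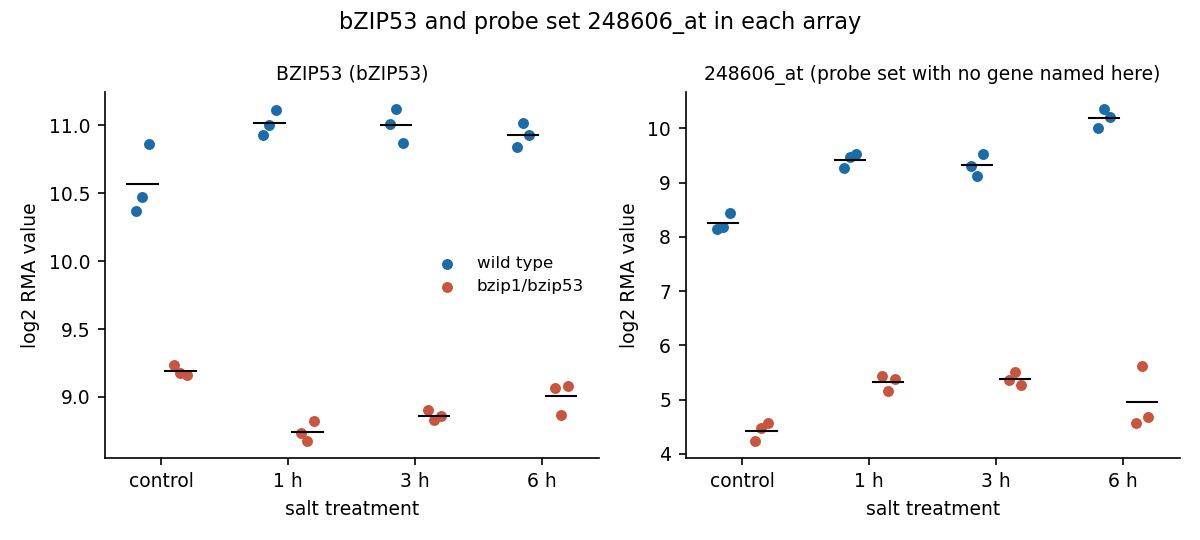
Log2 RMA values of BZIP53 (left) and of the unnamed probe set with the largest genotype difference (right) in each array, by salt treatment and genotype; points are arrays and bars are the means of 3 arrays. Mutant BZIP53 values lie between 8.67 and 9.24, below the lowest wild-type value of 10.37.

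After 1 h of salt, the transcription factor gene ORA47, of the AP2/ERF family, rose 20.7-fold in wild-type roots (4.37, SE 1.04, adjusted p = 0.00377), although its level differed widely between the control arrays (6.62 ± 2.9). AT4G28140 rose by an apparent 16.7-fold, over a control near the background, from 4.45 ± 0.13 to 8.51 ± 0.43 (adjusted p = 1.31e-10), and AT1G32970, AT5G52760, AT3G28600, AT2G26380, AT5G63130 and AT1G76640 rose by 3.41 to 3.88 (log2). The zinc finger repressor gene STZ (2.04) and WRKY53 (1.94) of the fixed list of stress transcription factors also rose. Among named genes with a call and no overlap, the largest decreases were those of AT1G19900, AT1G72200 and AT5G48290 (5.60-fold, 5.55-fold and 5.52-fold), followed by AT2G28970, AT1G66800, AT4G22460, AT4G14780 and AT3G49960 (-2.33 to -2.15). The expansin genes EXPA7 (-1.06) and EXPA18 (-1.69), which act in root hair growth, fell.

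Of the 6 measured desiccation genes (LEA and dehydrin genes), 4 rose at 1 h and 2 did not pass, 5 adjusted over the list alone. LTI30 rose by 1.79, LEA4-5 by 1.48 and COR47 by 0.71, whereas COR15A was at 0.84 without a call. Of 7 autophagy genes of the ATG8 family, 5 fell, 7 adjusted over the list alone, among them ATG8H (-0.68), ATG8F (-0.67) and APG8A (-0.63). The camera test gave an adjusted p of 0.00219 for both lists, and an adjusted p of 0.504 with an estimated correlation. Of 10 branched-chain amino acid breakdown genes, 1 rose and 2 fell, 4 adjusted over the list alone (adjusted p = 0.409). In total 5624 probe sets were called, 2122 higher and 3502 lower. Left-out arrays ended the calls of STZ (0.95 and 1.96 without control arrays 1 and 2, 2.07 and 1.79 without 1 h arrays 1 and 3), WRKY53 (1.42 and 1.61 without control arrays 1 and 2, 1.48 without 1 h array 3) and LEA4-5 (1.26 without 1 h array 3). The call of the desiccation gene AT3G53990 (0.24) ended without any array but 1 h array 2 (0.18 to 0.27). The 3 branched-chain calls ended too, that of ETFBETA without control array 3 (0.17) or 1 h array 1 (0.28) or 2 (0.22), D2HGDH without 1 h array 3 (-0.25), and ALDH6B2 without control array 2 or 3 or 1 h array 1 or 3 (-0.30 to -0.24). With a fold of at least 2 the count was 1160 (583 higher, 577 lower), and at an adjusted p under 0.01 it was 3505.

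After 3 h in wild type, AT2G41730 rose by an apparent 58.8-fold, from 4.44 ± 0.3 to 10.31 ± 0.067 (adjusted p = 9e-14), the small heat shock protein gene AT5G51440 49.2-fold, the LEA-family genes AT3G02480 and AT3G15670 44.3-fold and 33.3-fold, and GH3.3, which encodes an enzyme that conjugates auxin to amino acids, 37.5-fold (5.23, SE 0.191, adjusted p = 1.8e-13). The control levels of these 5 genes (3.56 to 4.59) lay near the background, so their folds here and at 6 h have no exact size. AT1G32970 and AT3G53600, also from near the background (4.05 and 3.997), and AT5G19110 rose by 5.06 to 5.27. XTH26, a xyloglucan endotransglucosylase, fell by an apparent 5.66-fold to a level near the background (4.38), and AT4G22460, AT3G18450, AT3G46270, AT1G70880, AT1G07690, AT1G72200 and AT4G30670 fell as well (-2.88 to -2.43).

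All 6 desiccation genes rose at 3 h, 6 adjusted over the list alone, with a median of 1.67. LEA4-5 reached 4.50 from a control level near the background (3.97), LTI30 2.37, COR15A 2.13 and COR47 1.22 (camera adjusted p = 5.19e-06; adjusted p = 0.233 with an estimated correlation). Of the 7 autophagy genes 5 fell (5 adjusted over the list alone; adjusted p = 0.0381, and 0.601 as adjusted p with an estimated correlation). Of the 10 branched-chain breakdown genes 5 fell and 1, ETFBETA (0.36), rose, with 6 adjusted over the list alone; MCCA (-0.58) and MCCB (-0.33) encode the subunits of an enzyme of leucine breakdown (adjusted p = 0.322). The proline dehydrogenase gene AT5G38710 rose by 2.27 and AT4G33150, of lysine breakdown, fell by 0.83. In total 8159 probe sets were called, 2812 higher and 5347 lower, and 1837 with a fold of at least 2 (1075 higher, 762 lower). Without control array 1, STZ was at 1.23 and no longer called, ETFBETA was at 0.23 without control array 3, and D2HGDH at -0.285 without 3 h array 1, both without a call. MCCA lost its call without control array 2 (-0.50), 3 h array 1 (-0.51) or 3 h array 2 (-0.43).

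After 6 h in wild type, AT2G41730 rose by an apparent 225-fold (7.82, SE 0.204, adjusted p = 5.21e-16), AT3G02480 130-fold, AT5G43450 123-fold, GH3.3 106-fold, AT3G15670 103-fold and LEA4-5 90.6-fold, and AT5G51440 and AT3G53600 rose 79.7-fold and 72.1-fold, all from control levels near the background (3.56 to 4.59). The methionine gamma-lyase gene MGL rose by 1.84, PPDK, for pyruvate orthophosphate dikinase, by 1.60, IVD, for isovaleryl-CoA dehydrogenase of leucine breakdown, by 1.25 and the glutathione reductase gene GR1 by 1.06. The control level of PPDK also lay near the background, so its rise has no exact size. AT1G70880 fell 10.5-fold, the peroxidase gene AT5G17820 6.41-fold, and AT3G18450, AT4G22460, AT1G62510, AT3G46270, AT1G72200 and AT1G33840 fell too (-3.33 to -2.63).

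The 6 desiccation genes were all higher at 6 h, 6 adjusted over the list alone, with a median of 2.70 (adjusted p = 9.22e-06; adjusted p = 0.218 with an estimated correlation). COR15A had reached 3.30 and LEA18 2.81. Of the 10 branched-chain breakdown genes 5 rose and 2 fell, 8 adjusted over the list alone, with a median of 0.38 (adjusted p = 0.075); MCCB (0.55), ETFBETA (0.56), ETFQO (0.43) and D2HGDH (0.36) rose and ALDH6B2 (-0.64) fell. Of the autophagy genes 4 fell and ATG8H rose by 0.87, 5 adjusted over the list alone (adjusted p = 0.621). EXPA7 (-1.89) and EXPA18 (-2.04) remained lower. In total 10799 probe sets were called, 3724 higher and 7075 lower, and 2559 with a fold of at least 2 (1520 higher, 1039 lower). STZ lost its call without control array 1 (1.34, adjusted p = 0.0507).

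**Figure D2:**
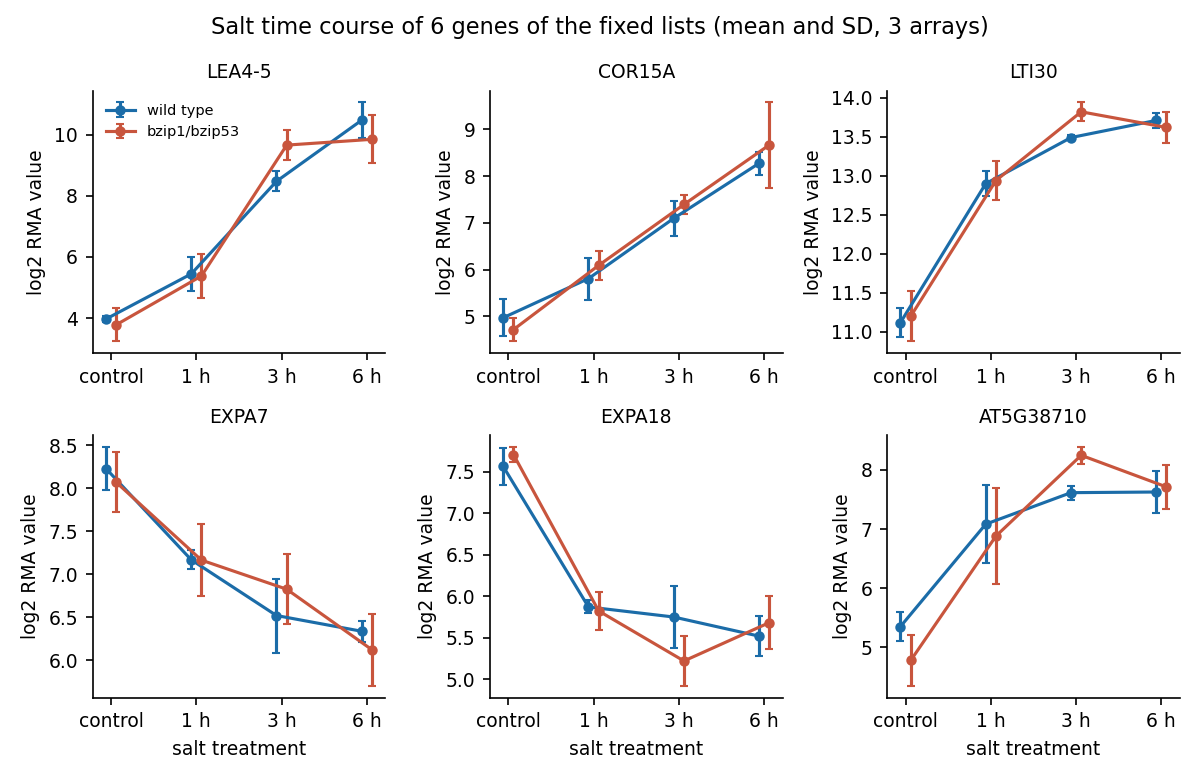
Log2 RMA values (mean and SD of 3 arrays) of 6 genes against salt treatment, with wild type in blue and bzip1/bzip53 in red. LEA4-5, COR15A, LTI30 and AT5G38710 were higher and EXPA7 and EXPA18 lower under salt in both genotypes.

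In wild type from 1 h to 3 h, 4 of 6 desiccation genes rose further, 5 adjusted over the list alone (LEA4-5 by 3.03, COR15A by 1.29; adjusted p = 3.02e-05, adjusted p = 0.164 with an estimated correlation), and 1 of 10 branched-chain breakdown genes, AT5G09300, fell (-0.43), with 2 adjusted over the list alone. From 3 h to 6 h, 6 of the 10 branched-chain genes rose and none fell, 6 adjusted over the list alone, with IVD at 1.58, MCCA at 0.99 and MCCB at 0.88 (adjusted p = 6e-06, adjusted p = 0.202 with an estimated correlation). MGL (1.87), PPDK (1.31), AT4G33150 (0.97) and ATG8H (1.01) rose in the same interval, as did 3 desiccation genes, 3 adjusted over the list alone (adjusted p = 0.015, adjusted p = 0.478 with an estimated correlation). The 3 h level of PPDK lay near the background. The autophagy list had 1 higher gene, ATG8H, in each interval, 1 adjusted over the list alone (adjusted p = 0.687 and 0.0362, the latter with adjusted p = 0.494 with an estimated correlation). From 1 h to 3 h 1903 probe sets were called, 992 higher and 911 lower, and from 3 h to 6 h 3388, 1540 higher and 1848 lower. The first count was 927 without 3 h array 1, 1012 and 1046 without 1 h arrays 2 and 1, and 1141 without 3 h array 2, and the second 2057 without 3 h array 3. Without 1 h array 1 or 2 the first calls of LTI30 (0.55 and 0.52), COR15A (1.18 and 1.14) and COR47 (0.48 and 0.44) ended, which left LEA4-5 of the 4 desiccation genes. Without 3 h array 2 the same 3 ended (0.57, 1.08 and 0.41), and without 3 h array 1 LTI30 (0.58) and COR47 (0.51). COR15A lost its second call without 3 h array 1 or 3 or 6 h array 1 or 3 (1.11, 1.03, 1.13 and 1.09). ATG8H from 1 h to 3 h lost its call without 3 h array 1 (0.44), and AT5G09300 without any array but 1 h array 3 (-0.44 to -0.35).

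In the mutant roots LEA4-5 rose by 1.60, 5.88 and 6.07 at 1 h, 3 h and 6 h, from a control level near the background (3.78). LTI30 rose by 1.74, 2.62 and 2.42, and AT5G38710 by 2.1, 3.47 and 2.94, while EXPA18 fell (-1.88, -2.48 and -2.02). Of the 6 desiccation genes 4, 6 and 5 rose and none fell, the same numbers adjusted over the list alone (adjusted p = 0.00307, 1.5e-05 and 6.48e-05; adjusted p = 0.36, 0.211 and 0.254 with an estimated correlation). Of the autophagy genes 4, 4 and 3 fell and 0, 1 and 1 rose, with 5, 5 and 4 adjusted over the list alone (adjusted p = 0.00568, 0.189 and 0.328; adjusted p = 0.36 with an estimated correlation at 1 h). Of the branched-chain breakdown genes 0, 2 and 1 rose and 0, 3 and 3 fell, with 0, 5 and 4 adjusted over the list alone (adjusted p = 0.684, 0.995 and 0.878). IVD rose by 0.58 at 3 h and 0.82 at 6 h, whereas MCCA stood at -0.37 and MCCB at -0.07 at 6 h without calls. Counts of called probe sets were 5473 (2400 higher, 3073 lower), 10342 (3957 and 6385) and 10899 (4125 and 6774). With only the 2 groups compared in the fit the 1 h count was 3557, and with array weights 8759. ATG8F and ATG8H lost their 1 h calls without mutant 1 h arrays 3 and 2 (both -0.36), and MCCB its 3 h call without control array 1 or 3 h array 1 or 3 (-0.29 to -0.21). LEA4-5 lost its 1 h call without mutant 1 h array 3 (1.28), and in the list PPDK (0.56 at 6 h) lost it without control array 1 (0.53) or 3 (0.54) or 6 h array 1 (0.53) or 2 (0.52). The mutant levels of PPDK in the control and at 6 h both lay near the background, so this rise has no exact size.

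Across the 22746 probe sets the salt responses of the genotypes, which share no arrays, correlated at r = 0.925 at 1 h, 0.922 at 3 h and 0.958 at 6 h; genes are not independent replicates. The slopes of mutant on wild type were 0.912, 1.15 and 0.991. Probe sets called higher in both genotypes numbered 1545, 2397 and 3157, against 223.9, 489.2 and 675.3 for independent lists, and those called lower in both 2419, 4261 and 5714, against 473.1, 1501 and 2107. Opposite calls numbered 2, 34 and 24.

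**Figure D3:**
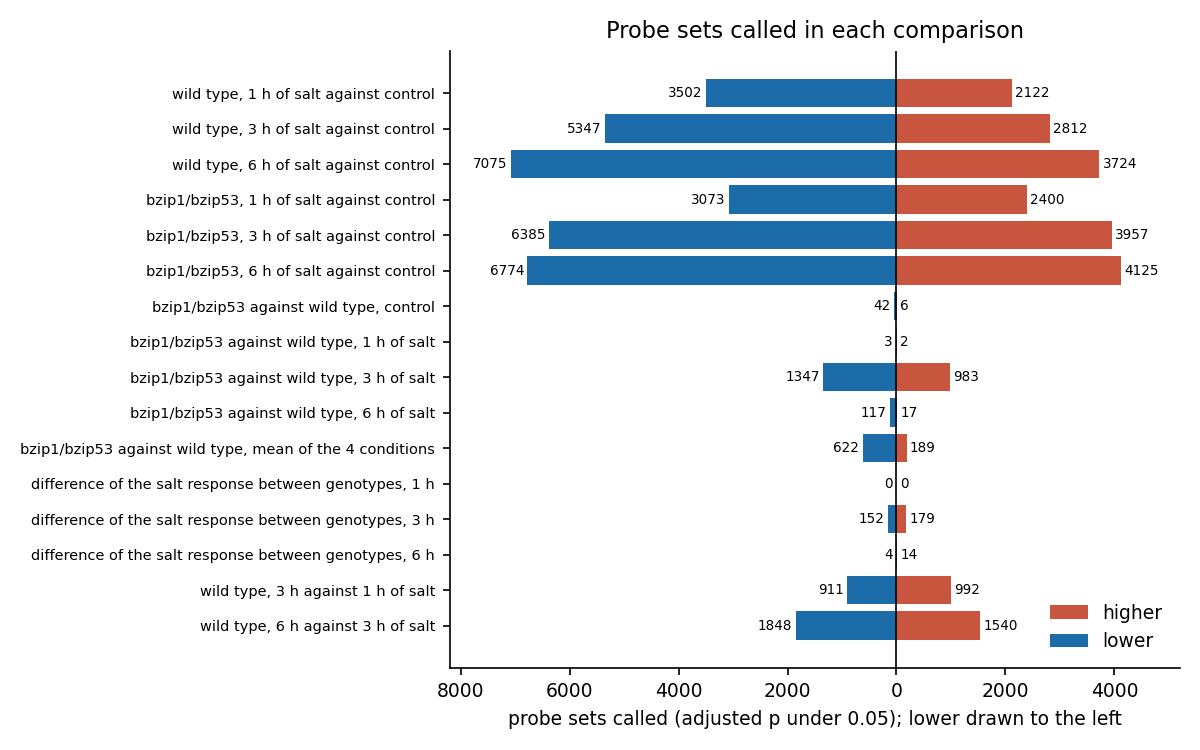
Numbers of probe sets called (adjusted p under 0.05) in each comparison, with lower calls drawn to the left and higher calls to the right of 0. Salt comparisons reach 10899 calls, and among the genotype comparisons of single conditions the 3 h one has the most, 2330.

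Without salt, genes of the plastid and mitochondrial genomes were lower in the mutant. The mitochondrial gene cox1 was lower by 2.67-fold (6.94 ± 0.35 against 8.35 ± 0.083, adjusted p = 0.000292), and the plastid genes rpl20 (-1.79, SE 0.319), ycf3 (-1.45), ycf4 (-1.39) and psaB (-1.37) were lower, beside BZIP53. Of 69 plastid-encoded genes 15 were lower and none higher, and of 15 mitochondrion-encoded genes 3 were lower; these lists were set up after the names were seen (adjusted p = 6.67e-37 and 5.7e-10; adjusted p = 0.103 for both with an estimated correlation). Mutant control array 1 stood apart beside these genes, with the lowest plastid median (6.62, against 7.07 and 7.095 in the other two), poly-A spike-in signal that no other array had (dap 8.198 against at most 3.43), a 3' to 5' gap of the actin probe sets of 1.4 and a 25S rRNA signal of 11.93 (12.52 to 12.71 in the other control arrays). The 25S signal was higher in every salt array of both genotypes (13.03 to 13.47) than in any control array, and the cause was not tested. Named genes higher in the mutant were AT3G05220 (0.47, adjusted p = 0.00489), AT1G10320 (0.69) and TPS-CIN, a terpene synthase gene (0.58). The largest increases among probe sets with no gene in the gene table were 1.19 and 0.64 (adjusted p = 7.59e-06 and 0.000154), given after their values were seen. The same probe sets were called higher at 1 h (1.23 and 0.49). None of the 10 branched-chain, 7 autophagy or 6 desiccation genes was called, nor adjusted over the list alone (adjusted p = 0.0719, 0.709 and 0.561).

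In this comparison 48 probe sets were called, 6 higher and 42 lower. The count was 17 without mutant array 1 and wild-type array 3 (chosen after seeing the data), 29 without mutant array 1 alone, 23 and 26 without wild-type arrays 1 and 2, 129 without mutant array 3, and 2 with only these 6 arrays in the fit. Leaving out 1 array ended the calls of rpl20 (without wild-type array 1, 2 or 3; -1.87 to -1.73), ycf4 (2 or 3; -1.41 and -1.17), psaB (1; -1.35), AT1G10320 (wild-type 1 or 3 or any mutant array; 0.63 to 0.78) and TPS-CIN (any array but mutant array 1; 0.45 to 0.605).

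After 1 h of salt, beside BZIP53, AT2G35920 was lower in the mutant, by 1.65-fold (7.25 ± 0.21 against 7.98 ± 0.063, adjusted p = 0.00201), and no gene with a name was higher. None of the members of the 3 fixed lists was called, nor adjusted over the list alone (adjusted p = 0.0995 for the autophagy, 0.254 for the branched-chain and 0.798 for the desiccation genes). In total 5 probe sets were called, 2 higher and 3 lower, of which 3 had no gene in the gene table (-4.11, 1.23 and 0.49; given after their values were seen). With array weights the count was 85.

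After 3 h, the beta-glucosidase gene BGLU27 was higher in the mutant by 4.66-fold (7.42 ± 0.4 against 5.197 ± 0.45, adjusted p = 0.00672), AT5G52680 by 4.98-fold and AT4G37290 by 4.75-fold (adjusted p = 0.000422), and AT5G60350, AT5G52670 and AT4G18250 by 1.87 to 1.90 (log2). AT3G29970 (-2.1), AT5G66985 (-2.06, adjusted p = 0.00494), AT2G17850 (-1.94), AT4G10270 (-1.83) and AT4G33560 (-1.72) were lower. These 5 are known to rise under low oxygen, and the other 19 of 24 such genes, a list written after these names were seen, had a median of -0.45 with 9 lower and 1 higher (camera p = 0.00021, p = 0.14 with an estimated correlation). In the other conditions these 19 had medians of 0.27 in the control (camera p = 0.00041, p = 0.16 with an estimated correlation), 0.17 at 1 h (p = 4.4e-05 and 0.11) and 0.18 at 6 h (p = 0.14 and 0.54), with 1 call, lower at 6 h. In the difference of responses at 3 h their median was -0.67 (p = 1.2e-07, and 0.041 with an estimated correlation). Among the fixed-list genes ATG8H (0.87), IVD (0.55) and AT3G53990 (0.34) were higher and ATG8B (-0.60) and the shoot marker RCA (-0.86) lower. Of the 6 desiccation genes 1 was higher, 3 adjusted over the list alone (adjusted p = 0.0103, adjusted p = 0.461 with an estimated correlation), and 2 of 7 autophagy and 1 of 10 branched-chain genes were called, 3 and 2 adjusted over the list alone (adjusted p = 0.753 and 0.632).

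The comparison had 2330 called probe sets, 983 higher and 1347 lower, and 247 with a fold of at least 2 (180 higher, 67 lower). With each array centred on its median the balance turned to 1246 higher and 977 lower. The count was 765 without mutant 3 h array 1, 1135 and 1123 without wild-type 3 h arrays 1 and 3, 1460 without mutant 3 h array 3, and 4883 with array weights. Without mutant array 1 the calls of AT3G29970 (-2.11), AT2G17850 (-1.88), AT4G10270 (-1.84), AT5G52670 (1.76), IVD (0.52), AT3G53990 (0.28) and RCA (-0.81) ended. Without wild-type array 1 those of AT3G29970 (-1.66), AT2G17850 (-1.69), AT4G10270 (-1.60), AT5G52670 (1.63), IVD (0.45) and AT3G53990 (0.33) ended. The same held for AT5G52670 (1.8), IVD (0.41) and RCA (-0.51) without wild-type array 2, AT4G10270 (-1.71), AT5G52670 (1.75) and IVD (0.53) without mutant array 2, and AT3G29970 (-1.795) and IVD (0.61) without mutant array 3.

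After 6 h, genes of the fixed list of branched-chain amino acid breakdown were lower in the mutant. MCCA was lower by 2.44-fold (8.11 ± 0.32 against 9.39 ± 0.24, adjusted p = 0.00128), and MCCB (-0.81), IVD (-0.79), D2HGDH (-0.62) and ETFQO (-0.50), which passes electrons to ubiquinone, were lower too. PPDK was lower by an apparent 2.44-fold (4.70 ± 0.099 against 5.99 ± 0.54, adjusted p = 0.00236), the sugar transporter gene SWEET4 by 3.72-fold (adjusted p = 0.0027), the response regulator gene RR16 by 2.92-fold (adjusted p = 0.00153) and GAT1_2.1, for a glutamine amidotransferase-like protein, by 2.44-fold (adjusted p = 0.0363). The mutant levels of PPDK, SWEET4 (4.71) and RR16 (3.80) lay near the background, so these folds have no exact size. AT4G33150 of lysine breakdown (-0.84) and the dark- and starvation-induced genes AKINBETA1 (-0.69) and AT3G15450 (-0.53) were lower, and MGL stood at -1.21 without a call.

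Of the 10 branched-chain breakdown genes 5 were lower and none higher, 7 adjusted over the list alone, with a median of -0.47 (camera adjusted p = 7.8e-13; adjusted p = 0.0501 with an estimated correlation). No desiccation or autophagy gene was called, nor adjusted over the list alone (adjusted p = 0.461 and 0.249). Among named genes with a call and no overlap, the largest increases were small, AT2G26500 at 0.82, AT5G50130 at 0.65, ATLP-1 at 0.58, AT3G01010 at 0.53, AT5G05960 and AT3G08030 at 0.49. In total 134 probe sets were called, 17 higher and 117 lower. Mutant 6 h array 1 had weak 5' signal, with actin and GAPDH gaps of 1.57 and 1.5 (log2, 3' minus 5'). The count was 45 without it, 40 without mutant array 3, 64 without wild-type array 1, 465 without mutant array 2, 326 with array weights and 3 with only these 6 arrays in the fit. Without mutant array 1 the calls of the 6 higher genes (0.76, 0.57, 0.55, 0.41, 0.44 and 0.47 in the order above), ETFQO (-0.42), AKINBETA1 (-0.55), AT3G15450 (-0.43) and GAT1_2.1 (-1.265) ended. These calls also ended without mutant array 3 (0.68, 0.62, 0.46, 0.53, 0.39 and 0.38 for the higher genes, and ETFQO -0.54, AKINBETA1 -0.66, AT3G15450 -0.48, GAT1_2.1 -1.22). All but AKINBETA1 ended without wild-type array 1 (0.515 to 0.68 and -1.405 to -0.50), and all but ATLP-1 and AT3G15450 without wild-type array 2 (0.41 to 0.85 and -1.17 to -0.42). ATLP-1 (0.53), AT5G05960 (0.49), AT3G15450 (-0.51) and GAT1_2.1 (-1.29) ended without wild-type array 3.

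**Figure D4:**
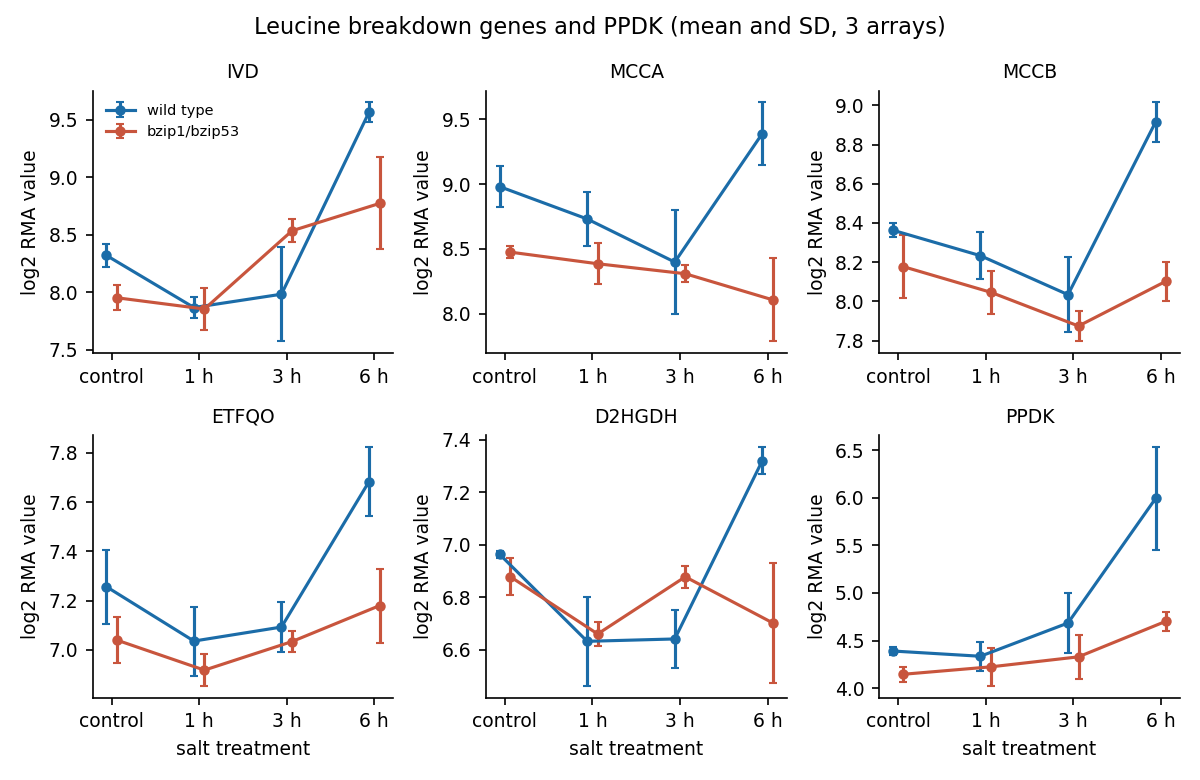
Log2 RMA values (mean and SD of 3 arrays) against salt treatment, wild type in blue and bzip1/bzip53 in red. Shown are IVD, MCCA, MCCB, ETFQO and D2HGDH of the branched-chain amino acid breakdown list, and PPDK. At 6 h wild type was higher than the mutant in all 6 panels.

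Over the mean of the 4 conditions, BZIP53 was at -1.93 in the mutant against wild type (SE 0.051), followed among the fixed-list genes by MCCA (-0.56), PPDK (-0.50), MCCB (-0.34), ALDH6B2 (-0.28), ATG8B (-0.26) and ETFQO (-0.22). Of the branched-chain genes 4 were lower, 5 adjusted over the list alone (adjusted p = 0.000261; adjusted p = 0.586 with an estimated correlation), of the autophagy genes 1, with 1 adjusted over the list alone (adjusted p = 0.777), and of the desiccation genes 0, with 0 adjusted over the list alone (adjusted p = 0.191). In total 811 probe sets were called, 189 higher and 622 lower, 98 at an adjusted p under 0.01 and 3 with a fold of at least 2, all lower. The split depended on the scaling, with 75.1% higher after each array was centred on its median against 23.3%, and ATG8B lost its call without wild-type 1 h array 2, mutant 1 h array 3 or mutant 3 h array 1 (-0.25 to -0.24). The count was 448 and 430 without wild-type control arrays 1 and 2, 458, 280 and 1251 without wild-type 1 h arrays 1, 2 and 3, 343 without wild-type 3 h array 3, 481 and 456 without wild-type 6 h arrays 1 and 2, 429 and 268 without mutant 1 h arrays 1 and 3, and 313 and 505 without mutant 3 h arrays 1 and 3.

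The difference of the salt responses asks whether the mutant responded otherwise than wild type. At 3 h the response of AT5G14230 was larger in the mutant by 1.40 (SE 0.147, adjusted p = 0.000169), and those of AT4G23590 (1.72), AT1G72850 (1.27), AT2G26690 (1.18), AT1G63820 (1.1), AT5G05880 (0.78), ATG8H (0.89) and AT3G15450 (0.65) were higher as well. Responses of AT3G27950 (-1.21), AT4G00670 (-1.15) and BZIP53 (-0.76) were lower. At 6 h, 7 of the 8 named genes with the smallest p were of organelle genomes. These were ycf3 (1.96), cox1 (1.90, SE 0.24, adjusted p = 0.00338), petL (1.63), rpoC2 (1.48), nad4 (1.40), matK (1.22) and rps2 (1.03), and the other was AT2G18420 (-0.95). Of 69 plastid-encoded genes 6 were called, all higher, with a median of 0.82 (adjusted p = 4.67e-55; adjusted p = 0.0412 with an estimated correlation). The control arrays of this comparison include mutant array 1 with its spike-in signal.

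At 1 h no probe set passed the limma test (0 called, 830 at an unadjusted p under 0.05, and 4 called with a trended and robust prior), and BZIP53 stood at -0.89 (adjusted p = 0.08). None of the 10 branched-chain genes was called at any time, with 0, 1 and 3 adjusted over the list alone and a median of -0.31 at 6 h (adjusted p = 1.93e-07; adjusted p = 0.133 with an estimated correlation); at 1 h and 3 h the adjusted p was 0.823 and 0.137. PPDK was at -1.04 at 6 h without a call. Of the autophagy genes ATG8H alone was called, at 3 h (1 adjusted over the list alone), and of the desiccation genes 0 were called (0 adjusted over the list alone). At 3 h 331 probe sets were called, 179 higher and 152 lower (130 and 219 with each array centred on its median), and 18 at 6 h, 14 higher and 4 lower. Without control array 1 of the mutant and control array 3 of wild type together these were 15 and 5.

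Leaving out single arrays changed both counts. At 3 h it was 210, 187 and 65 without wild-type control arrays 1, 2 and 3, 98 and 197 without wild-type 3 h arrays 1 and 2, 143, 167 and 188 without mutant control arrays 1, 2 and 3, and 45 and 162 without mutant 3 h arrays 1 and 3. At 6 h it was 4, 9 and 8 without wild-type control arrays 1, 2 and 3, 7 and 34 without wild-type 6 h arrays 1 and 2, 41 without mutant control array 3, and 5, 39 and 7 without mutant 6 h arrays 1, 2 and 3. The 3 h call of ATG8H ended without wild-type control array 3 (0.79), mutant control array 1 (0.87) or mutant 3 h array 1 (0.82), and that of AT3G15450 without any of 11 of the 12 arrays (0.55 to 0.69; all but wild-type 3 h array 3). The 6 h calls of rps2 (0.94 to 1.02), petL (1.45 to 1.66), ycf3 (1.85 to 2.02) and AT2G18420 (-1.02 to -0.82) ended without wild-type control array 1, mutant 6 h array 1 or mutant 6 h array 3. They also ended without wild-type control array 2 for petL, ycf3 and AT2G18420, wild-type control array 3 for ycf3 and AT2G18420, wild-type 6 h array 1 for rps2, ycf3 and AT2G18420, wild-type 6 h array 3 for ycf3 and mutant control array 1 for AT2G18420.

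**Figure D5:**
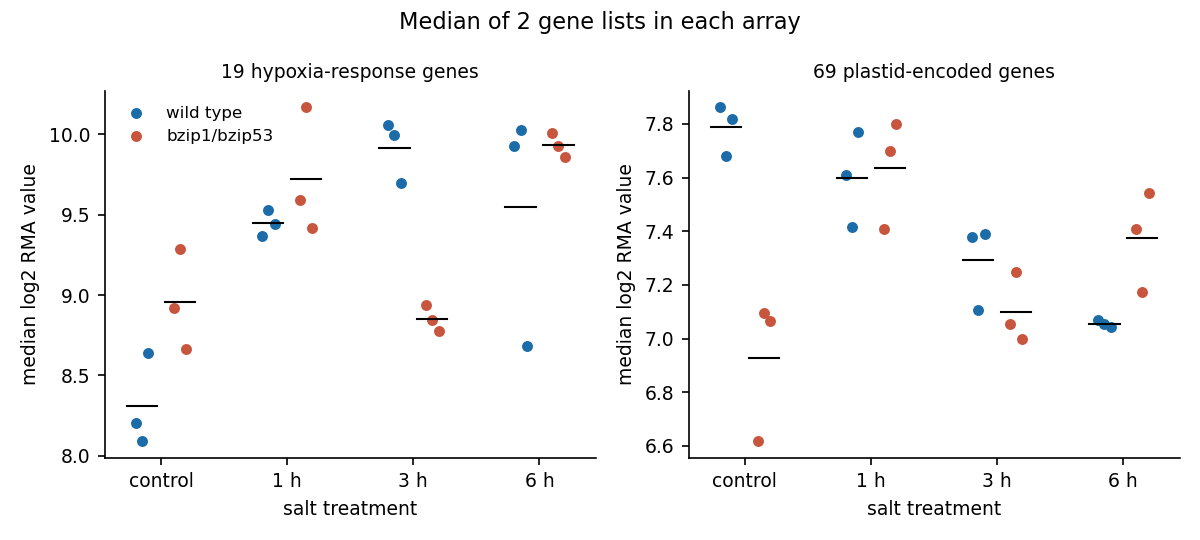
Median log2 RMA value in each array of 19 hypoxia-response genes (left) and of 69 plastid-encoded genes (right), by salt treatment and genotype; points are arrays and bars are means of 3 arrays. The 3 mutant arrays at 3 h (8.77 to 8.94) lie below the 3 wild-type arrays (9.70 to 10.06), and the plastid median of mutant control array 1 is the lowest at 6.62.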

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

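The tests chosen after the result was seen were all those on the plastid-encoded genes, those of the 3 h comparison, although its counts without single arrays were planned, and those of late risers and late induction at 6 h. The groups of 3 arrays were not tested for single outlying arrays.

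Differences between groups were noted where a test of the difference itself passed. The difference of the salt responses gave 331 called probe sets at 3 h and 18 at 6 h, and in wild type 1903 differed between 1 h and 3 h and 3388 between 3 h and 6 h. At 3 h the responses differed (mutant minus wild type, log2) for AT5G14230 (1.40), AT2G26690 (1.18), AT1G72850 (1.27), AT4G23590 (1.72), AT5G05880 (0.78), AT1G63820 (1.1), AT3G27950 (-1.21), AT4G00670 (-1.15), BZIP53 (-0.76), AT3G15450 (0.65) and ATG8H (0.89). At 6 h they differed for cox1 (1.90), matK (1.22), rpoC2 (1.48), nad4 (1.40), rps2 (1.03), petL (1.63), ycf3 (1.96) and AT2G18420 (-0.95). The 64 Affymetrix control probe sets were left out of the comparisons described, and in a fit of their own 2 to 10 were called under salt against control and 0 between genotypes. They showed poly-A spike-in signal in mutant control array 1 alone, with dap at 8.198 (3.013 to 3.425 in the other 23 arrays), thr at 7.022 (3.364 to 3.82), phe at 5.163 (2.893 to 3.322) and lys at 4.571 (3.151 to 3.507).

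Plastid-encoded transcripts were lower in the mutant control, with a median difference of -0.55 over 69 genes. The tables argue against array 1 of the mutant control alone and against weaker 5' signal of the RNA, since mutant control arrays 2 and 3, whose actin gap lay inside the range of the wild-type controls, had plastid medians below the lowest wild-type control by more than the range of those controls (-0.58 against 0.18), although the median difference shrank to -0.37 without array 1. They also argue against a genotype effect of the same size in all conditions, as the medians were -0.0049 at 1 h, -0.26 at 3 h and 0.23 at 6 h. Less green tissue in the mutant samples stays open, since the 16 nuclear photosynthesis genes (median difference -0.14, quartiles -0.33 and 0.00097) lay near the background, at a median level of 4.9 against 6.6 for all probe sets. A difference between the control cultures or in the time of harvest, and an effect of genotype in unsalted roots only, were not tested.

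Many probe sets differed between genotypes at 3 h (2330 called), and array 1 of the mutant at 3 h alone is argued against, since 765 were called without it, still more than in any other condition. Mutant roots further along the salt response could account for part of it, since the 3 h difference correlated across probe sets with wild type 6 h minus 1 h, which shares no arrays with it, at 0.51 (0.075, 0.17 and 0.11 for like comparisons of the other conditions), and 85.7% of the called probe sets had the same sign; genes are not independent replicates. The 3 h difference correlated as much, at 0.5, with the main direction of variation within groups, so 0.51 does not single out progress along the response. Samples that differed in handling or oxygen supply could account for the lower hypoxia-response genes, whose median was -0.45 for the 19 genes that did not lead the comparison. The same genes differed by as much between 2 arrays of a group in 2 of the 8 groups (medians of 0.61 in wild type at 6 h and 0.54 in the mutant at 1 h), but by 0.3 and 0.041 in the wild-type and mutant groups at 3 h, so this and an effect of the lesions on the pace of the response remain open. These values are the largest differences between single arrays of a group. Such differences vary more than one between means of 3 arrays, so they compare only loosely with -0.45.

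Branched-chain breakdown genes were lower in the mutant at 6 h, with a median of -0.47. A single array is argued against, since the highest median with 1 of the 6 arrays left out was -0.39. Mutant roots less far along the salt response stay open, although probe sets that rose in wild type from 3 h to 6 h, chosen by 1 of the 6 h arrays and compared with the other two, had medians of only -0.11, -0.057 and -0.024 in the mutant against wild type, beside rises of 0.95, 0.39 and 0.68, because with array 2 as the choice the lower quartile (-0.23) was larger in size than 0.5 times the rise. The 992 probe sets that rose from 1 h to 3 h, the planned test, had a median of 0.0016 at 6 h but need not lag then, so they do not decide it. Weaker late induction goes with a median change from 3 h to 6 h of -0.15 in the mutant against 0.42 in wild type and with genotype medians of -0.11 at 1 h and -0.022 at 3 h, but the control median of -0.16 missed the bound of -0.1, so a part already present without salt is not excluded, and a role of the mutated genes in this pathway is untested.

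Other splits of the arrays were counted for each comparison. With 6 arrays there were 10 splits, too few for a share under 0.05, and 1 of them, the real one, called the most in the salt comparisons. The real counts and the highest of the others were 5624 and 0, 8159 and 0, and 10799 and 0 in wild type at 1 h, 3 h and 6 h, 5473 and 0, 10342 and 1, and 10899 and 5 in the mutant, and 1903 and 0, and 3388 and 2, for the later times in wild type. Between genotypes they were 2330 and 1 at 3 h and 134 and 49 at 6 h. Each of the other splits mixed arrays of the compared groups, so a true difference entered the spread of its fit and lowered its count. The low counts are therefore not rates of false calls. In the control and at 1 h, 2 of the 10 splits reached the real count, with 48 against 130 for a split that put wild-type control array 3 with mutant control arrays 1 and 2, and 5 against 88 for 1 that put wild-type 1 h array 3 with mutant arrays 1 and 3. Counts several times the real one point to a structure of the samples other than genotype. For the mean of the conditions 1 of 100 splits, the real one, reached 811, and the others at most 1, a share under the bound of 0.05. This speaks against a random division of the arrays, but it does not tell genotype from another difference between the samples. The count of 811 itself ran from 268 to 1251 with 1 array left out. For the difference of responses at 1 h the real count was 0, which all 100 splits reach whatever the data (highest 565). At 3 h 5 of 100 reached 331 (highest 1358), so chance cannot be excluded. At 6 h 3 of 100 reached 18 (highest 274), a share under the bound of 0.05. That share rests on 100 draws and was not adjusted over the comparisons, so it does not firmly exclude chance. At 3 h and 6 h the highest of these splits again called several times the real counts. Labels were shuffled within each condition, so a split could keep or swap the real genotypes in 1 condition and still carry a genotype difference. These counts therefore do not tell another structure of the samples from genotype. The shares of 5 and 3 in 100 are limited in the same way.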

How the results depend on the processing

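The test without array 3 of the wild-type control and array 1 of the mutant control was chosen after the result was seen, and all other alternatives were planned. No called difference of a named gene changed sign under an alternative, and no gene list was called in opposite directions. The balance of higher and lower calls was less stable. Centring turned it for the genotypes at 3 h (983 higher and 1347 lower to 1246 and 977), their mean (189 and 622 to 632 and 210), the difference of responses at 3 h (179 and 152 to 130 and 219) and 6 h against 3 h in wild type (1540 and 1848 to 1683 and 1647), and a fold of at least 2 turned it in all salt comparisons, the genotypes at 3 h (180 and 67) and 6 h against 3 h (427 and 30). For 3 h against 1 h (992 and 911) it turned with array weights (1451 and 2046), without dim probe sets (1022 and 1054) and without 1 h array 3 (1038 and 1183), and for 6 h against 3 h with only the arrays compared (1042 and 930), at an adjusted p under 0.01 (854 and 746) and without 3 h array 3 (1042 and 1015) or 6 h array 3 (1228 and 1125). It also turned for the difference of responses at 3 h after quantile normalization (133 and 178) and without wild-type 3 h array 2 (88 and 109), at 6 h without wild-type 6 h array 2 (16 and 18), for the genotypes at 1 h with array weights (43 and 42) and for gene lists with fry (49 and 33 to 46 and 101). The counts of probe sets called for salt against control in both genotypes stayed within 1.5 times under the replicate block, both other scalings, the filter on dim probe sets and the trended and robust prior. With each array left out in turn they ran from 4173 to 5091 for wild type at 1 h, 6631 to 7391 at 3 h and 9550 to 10357 at 6 h, and in the mutant from 3914 to 5032, 9127 to 9999 and 9826 to 10658. For mutant against wild type these ranges were 23 to 129 in the control, 4 to 6 at 1 h, 765 to 1819 at 3 h, 40 to 465 at 6 h and 268 to 1251 over the mean of the conditions. For the difference of the salt responses they were 0 to 7 at 1 h, 45 to 277 at 3 h and 4 to 41 at 6 h. For 3 h against 1 h in wild type the range was 927 to 2221, and for 6 h against 3 h 2057 to 2931. A required fold of at least 2 left fewer calls because it removes small changes by construction: 1160, 1837 and 2559 in wild type, 1150, 2667 and 2738 in the mutant, 19, 3, 247 and 19 for the genotypes in the control and at 1 h, 3 h and 6 h, 3 over their mean, 132 for the difference of responses at 3 h, and 315 and 457 for the later times in wild type. An adjusted p under 0.01 is likewise stricter by construction and left 3505 (wild type, 1 h), 3239 (mutant, 1 h), 14 (genotypes, control), 728 (3 h), 45 (6 h), 98 (mean), 7 and 3 (difference of responses at 3 h and 6 h) and 852 and 1600 (later times). With only the arrays compared in the fit, which leaves fewer arrays for the spread, the counts were 3557 (mutant, 1 h), 2 (genotypes, control), 3 (1 h), 3 (6 h), 635 and 3 (difference of responses at 3 h and 6 h) and 1217 and 1972 (later times). That alternative was void for the mean of the conditions, which uses all arrays. Array weights gave 8759 (mutant, 1 h), 85, 4883 and 326 (genotypes at 1 h, 3 h and 6 h), 3389 (mean), 1, 1046 and 35 (difference of responses at 1 h, 3 h and 6 h) and 3497 and 5328 (later times); the cause was not tested. Quantile normalization again gave 31 (genotypes, control), 360 (mean) and 1 and 10 (difference of responses at 1 h and 6 h), centring 1 at 1 h, and the trended and robust prior 4 at 1 h; the cause was not tested. Without the 2 control arrays the counts were 17 (genotypes, control) and 1, 15 and 5 (difference of responses at 1 h, 3 h and 6 h), with fewer arrays by construction. Another scaling moved the share of higher calls in the genotype comparisons, from 12.5% to 37.8% in the control, 42.2% to 56.1% at 3 h, 12.7% to 26.1% at 6 h and 23.3% to 75.1% over the mean, all after centring, and to 35.3% over the mean after quantile normalization. For the difference of responses it moved from 54.1% to 37.2% (centred) and 42.8% (quantile) at 3 h and from 77.8% to 56% and 90% at 6 h. The correlations of the salt responses of the genotypes were 0.972, 0.954 and 0.975 over the probe sets called in wild type, and 0.929 and 0.966 at 3 h and 6 h without the dim ones. The number of gene list calls, 82, became 1 with an estimated correlation, and 147 with fry, which tests a list without comparing it with other genes. An estimated correlation widens the null spread of a list where the estimate from these arrays exceeds the preset 0.01. With the replicate number as a block, the counts were 5701, 8203 and 10799 in wild type, 5531, 10340 and 10914 in the mutant, 43, 5, 2331, 161 and 826 for the genotypes in the 4 conditions and their mean, 0, 314 and 15 for the difference of responses, 1913 and 3362 for the later times and 79 for gene lists, all within 1.5 times of those without it. The block ended 7 calls of named genes and 3 of gene lists. Deviations of arrays with the same replicate number in different groups correlated at 0.0096 on average (-0.558 to 0.719), against -0.0031 for different numbers, and 10 of 24 arrays correlated best with their own number. The numbers thus showed no pairing common to all groups. Pairing within 1 time only was not tested. Along the main direction of variation within groups, 1 h arrays of equal number lay alike. They stood at -0.06, -0.26 and 0.32 in wild type and at 0.025, -0.33 and 0.31 in the mutant. Control arrays did not (-0.25, -0.18 and 0.43 against 0.32, -0.11 and -0.21). The block, 1 effect per number for all groups, would not take up a pairing within 1 time. Of the values of single named genes, 8988 were on the same side of the threshold, 345 lost and 67 gained a call, 234 of the losses with an array left out. Of the gene list values 2107 stayed, 116 lost and 97 gained a call. For probe sets near the background, signal limits which differences can be detected.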

Other observations

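The tests in this part, on gene families named after the gene table had been seen and on the main direction of variation within groups, were chosen after the result was seen. Members of further gene families were called under salt in wild type. Of all probe sets, 24.7%, 35.9% and 47.5% were called at 1 h, 3 h and 6 h, and 14.9% from 3 h to 6 h. Of 9 PUB genes, of the U-box ubiquitin ligases, 4, 6 and 5 rose and none fell at 1 h, 3 h and 6 h (camera adjusted p = 0.00853, 0.00393 and 0.00795, and 0.504, 0.368 and 0.474 with an estimated correlation), with PUB19 at 2.87, 3.74 and 3.66 and PUB24 at 1.54, 2.29 and 2.82. Of 20 beta-glucosidase genes 8 rose and 3 fell at 6 h (adjusted p = 0.00795, and 0.327 with an estimated correlation). BGLU24 was at 2.15, 5.03 and 5.94 over the 3 times, BGLU27 at 4.51 and BGLU40 at 2.37 at 6 h. Of 7 Aux/IAA genes, which encode repressors of the auxin response, 4 rose and 1 fell at 6 h (adjusted p = 0.0214, and 0.218 with an estimated correlation), with IAA30 at 1.62, 3.46 and 4.39 and IAA29 at 1.55. Of 22 TBL genes, for acetylation of wall polysaccharides, 13 fell and none rose at 6 h (adjusted p = 0.00972, and 0.218 with an estimated correlation), among them TBL21 (-1.95), TBL41 (-1.29) and TBL34 (-1.28). Of 12 cell division genes 10 fell at 6 h (adjusted p = 0.00412, and 0.327 with an estimated correlation), with 3xHMG-box1 at -1.33, 3xHMG-box2 at -1.05 and AUR1 at -0.91. From 3 h to 6 h 5 of these genes fell (adjusted p = 0.000125, and 0.202 with an estimated correlation), as did 4 tubulin genes, TUB1 (-1.0) and TUB5 (-0.64) among them (adjusted p = 0.00497, and 0.33 with an estimated correlation). Of 14 SWEET sugar transporter genes 5 rose and none fell in that interval (adjusted p = 0.0116, and 0.153 with an estimated correlation), among them SWEET4 (2.82), SWEET8 (0.66) and SWEET13 (0.63). SWEET4 rose from a level near the background, so its rise has no exact size.

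Of the 19 hypoxia-response genes that did not lead the genotype comparison at 3 h, 13 were called higher and 4 lower in wild type at 3 h (median 0.86; camera p = 8.3e-05, and 0.12 with an estimated correlation) and 11 higher and 2 lower at 6 h (median 0.87; camera p = 0.00044, and 0.16 with an estimated correlation). Of the 69 plastid-encoded genes 3, 0 and 0 were called higher and 1, 14 and 35 lower in wild type at 1 h, 3 h and 6 h, and 38, 6 and 22 higher and 0, 6 and 2 lower in the mutant, whose control levels were lower. In the difference of responses none was called at 1 h (adjusted p of the list = 1.71e-39, and 0.0724 with an estimated correlation) or 3 h (0.000415, and 0.617 with an estimated correlation), and 6 at 6 h as described.

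Within groups, arrays differed along 1 main direction, which held 37.5% of the variance left after the group means. Wild-type control array 3 (0.43), mutant control array 1 (0.32), wild-type 1 h array 3 (0.32) and mutant 1 h array 3 (0.31) lay at its upper end, and mutant 1 h array 2 (-0.33), wild-type 1 h array 2 (-0.26) and wild-type control array 1 (-0.25) at its lower end. Its leading genes included AT1G19210, AT3G01830, CML37 and ORA47, which differed by 4.89, 4.83, 5.37 and 5.25 (log2) between the wild-type control arrays. At its low end were AT4G10270, AT2G17850 and AT5G66985 (1.56, 1.34 and 0.80), which are among the genes lower in the mutant at 3 h. Across probe sets the direction correlated at 0.54 with the wild-type salt response at 1 h, at 0.5 with the genotype difference at 3 h and at 0.55 with the mean genotype difference; genes are not independent replicates, and no explanation was tested.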
